A study of Mus musculus with 8 samples.

How the data were processed

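White adipose tissue RNA was measured by sequencing in 8 libraries from female C57BL/6J mice, 4 from mice given phosphate-buffered saline and 4 from mice given endostatin at 50 mg/kg by tail vein, with tissue taken 2 h later. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into strand-specific libraries with dUTP. The labels place 2 libraries of each group in each of 2 batches. The description of endostatin 4 gives its own library name but repeats the read file stub of endostatin 3; the counts of these libraries differ (Pearson correlation 0.934 across genes), and the labels were kept. The series text speaks of 4 female mice without saying whether this is per group, and the labels do not tie each library to an animal, so the p-values measure the spread between these samples, which may be technical in part.

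The deposited files hold transcript-level estimated counts from Salmon, per the submitters' processing notes, which name the GRCm39 build; the version, index and options are not given in the sources used here. The same deposited files hold TPM, transcript abundances that the authors' run of Salmon scaled to the same total in each library. They also give effective transcript lengths. Each file lists 115620 transcripts. Their identifiers were matched, without the version suffix, to the GENCODE M21 transcript set, which was used only for gene names and gene types: 113710 (98.35%) matched, and the 1910 others were kept as features of their own. M21 belongs to an older build and carries no later symbols, and no coordinates are printed because no annotation of the submitters' build was analysed here. Estimated counts were summed per gene and rounded to whole numbers, giving 37046 features. Salmon divides reads between transcripts that share sequence, so values of near-identical genes and overlapping genes are uncertain.

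The total estimated count was 15826783 to 19221886 in the 4 control libraries and 17197721 to 23786594 in the 4 endostatin libraries. A count of 0 allows up to 3 counts, which is 0.126 to 0.19 CPM (counts scaled to library size) in a single library; this floor covers counting error only. TPM was used only for summed marker levels per library.

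Features with low counts were removed with edgeR's filterByExpr, which left 15184 genes. Counts were normalised by TMM and fitted with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with terms for batch and treatment. The batch term of that fit gave the batch comparison, and a model with the batch by treatment interaction gave the within-batch log2 fold changes and the test of their difference. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Intervals are 95% intervals from the quasi-likelihood fit. CPM values were normalised by the TMM factors.

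The tests, 39 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule names up to 12 genes per direction past the threshold or, when none pass, the 6 genes of each direction with the smallest unadjusted p and a mean of at least 1 CPM. It also names up to 2 members of each list per direction with the smallest p, 18 genes reported whatever their values, and 4 genes per direction for the batch and interaction comparisons. Of the 18, Il6 was below the count filter and was not tested. Predicted genes and pseudogenes were counted, and any that are named were chosen after their values were seen.

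Gene lists covered adipocyte metabolism, signalling responses, mitochondrial transcripts and markers of cell types and neighbouring organs. A list with at least 3 tested members, of which there were 36, was tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, with camera with an estimated correlation, and with fry, on log2 CPM with a prior count of 2 and the same model. The preset correlation is far below the correlation estimated in most lists of cell type or metabolism, and both adjusted p values are given. Some signalling lists had estimates near or below the preset value (NF-kB 0.024, angiogenic -0.0009, MAPK feedback -0.046). For the angiogenic list camera's unadjusted p was 0.024 with the preset and 0.047 with the estimate. The size of the correlation is thus not the only difference between the 2 tests. A further 5 marker lists (hepatocytes, mesothelial markers outside the keratins, epithelial keratins and junction genes, kidney, mammary gland) were written after the libraries' values were seen and describe the makeup of the samples only.

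Alternatives covered other size factors, a robust fit, a threshold of 0.1, DESeq2 1.42.0, limma-voom with and without sample quality weights, 1 surrogate variable (sva 3.50.0), other count filters, transcript length offsets, protein-coding genes alone, leaving out mitochondrially encoded genes, no batch term, a block on the replicate number, and leaving out each library in turn. Leaving out control 3 with endostatin 4, and control 1 with control 4, was added after seeing the data. The 35 ways of dividing the 8 libraries into 4 and 4 were also fitted. Tables and plots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

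The fits were tested on simulated counts drawn from the real means and library sizes, in 3 runs per comparison with 200 changed genes each. For the treatment term, the test recovered 8.0% of genes changed by 1.5-fold, 45.3% at 2-fold, 74.0% at 3-fold and 88.0% at 4-fold, with 18 false calls among 341. For the interaction, it recovered 0 of 150 genes at 2-fold and 27.3% at 4-fold. For the batch term, it recovered 42.7% at 2-fold and 78.7% at 4-fold. The simulation draws genes independently, so it does not carry the correlation between genes or the mixture of tissues found in the real libraries.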

Results

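Gene expression was measured in white adipose tissue of female C57BL/6J mice, an inbred laboratory strain, 2 h after a tail vein injection of endostatin or vehicle. Endostatin is a fragment of collagen XVIII, the product of Col18a1, and is known as an inhibitor of blood vessel growth. Food was removed after the injection, and the tissue was taken during the day. The series asks how endostatin changes gene expression in this tissue. Each group had 4 libraries, 2 in each of 2 batches, with 15826783 to 23786594 estimated counts per library. In genes with a mean of at least 10 CPM, this design gave a 95% interval of the log2 fold change with a median width of 0.30 to either side. Levels are mean ± SD in CPM over the 4 libraries of a group, and log2 fold changes are endostatin minus control ± SE.

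The gene with the most counts was Scd1 or Fasn, enzymes of fatty acid synthesis, in 7 libraries and Car3, a carbonic anhydrase abundant in fat, in endostatin 4. Adipoq, which encodes adiponectin, stood at 2179 ± 696 CPM in the control group and 2199 ± 239 CPM in the endostatin group. The labels name the tissue as epididymal although the mice are female. Of 15 markers of epididymis and testis, 13 had less than 1 count over all libraries, as did 5 of 7 Y-linked genes. The others had counts in 8 of 8 libraries, with totals of 593 for Sycp3, 143.3 for Insl3, 277.7 for the Y-linked Kdm5d and 180 for the Y-linked Uty.

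The libraries differed in transcripts of other organs. A set of 26 hepatocyte transcripts, such as Alb (albumin), chosen after values were seen, summed to 193.1, 133.5, 20.4 and 31.9 TPM in control 1 to 4. They summed to 452.0, 696.1, 25 and 1339 TPM in endostatin 1 to 4. The libraries of batch 1 thus lay at 133.5 to 696.1 TPM, and in batch 2 endostatin 4 alone exceeded 31.9 TPM. Markers of oviduct and uterus summed to 850.3 TPM in control 3 and 560.7 TPM in endostatin 4, against 122.0 to 167.1 TPM in the other 6 libraries. In those 6, Esr1 alone gave 84.4 to 120.5 TPM. Among the 6, endostatin 1 was highest in Pgr (11.7 TPM), Msx1 (8.72 TPM), Ltf (2.41 TPM) and Epcam (2.34 TPM), but not in Ovgp1 or Foxj1. In endostatin 4, Ltf, which is also on the neutrophil list, gave 298.3 TPM of the sum. There, 8 of 13 genes were at over 2 times their median in the other 6 libraries. Skeletal muscle markers summed to 238.1 TPM in control 1 and 464.6 TPM in control 4, against 35.2 to 108.3 TPM in the other 6. Mitochondrially encoded genes held 4.23% to 5.19% of the counts in batch 1 and 2.13% to 3.31% in batch 2. The first principal component, with 33.7% of the variance, set control 3 (71.5) and endostatin 4 (48.8) apart from the other libraries (-34.0 to -6.6).

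**Figure D1:**
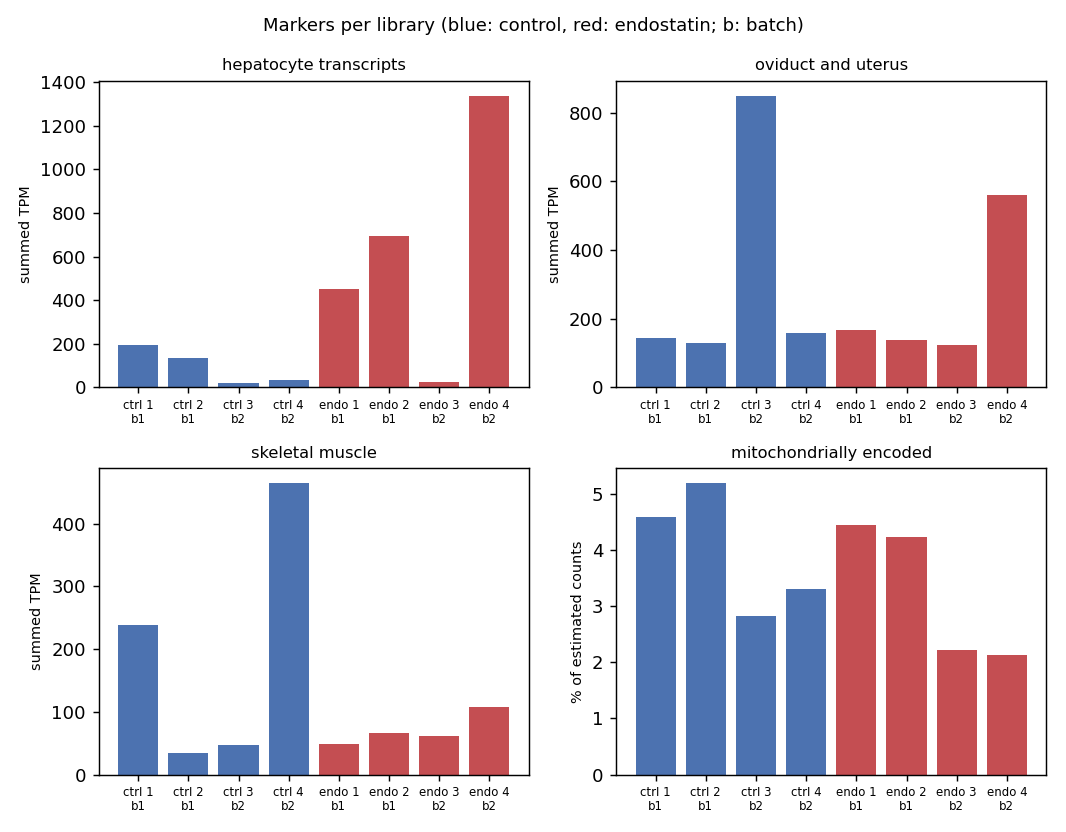
Summed TPM of hepatocyte, oviduct and uterus, and skeletal muscle markers, and the percentage of estimated counts in mitochondrially encoded genes, for each library (blue bars, control; red bars, endostatin; b1 and b2, batch). Hepatocyte transcripts reach 1339 TPM in endostatin 4, oviduct and uterus markers 850.3 TPM in control 3, and muscle markers 464.6 TPM in control 4, and the mitochondrial percentage is lower in each library of batch 2 than in each library of batch 1.

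At 2 h no gene passed the threshold between the endostatin and control groups in edgeR's quasi-likelihood test. Among 15184 genes, 0 were higher and 0 lower, and the lowest adjusted p was 0.409. The unadjusted p was under 0.05 for 485 genes, of which 349 had higher and 136 lower levels after endostatin, against 759 expected by chance. DESeq2 called 3 genes higher and 1 lower, limma-voom called 0, and limma-voom with sample quality weights called 1 higher.

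The 4 genes called by DESeq2 are named after their values were seen. Mup17 (ENSMUSG00000096688), of the family of major urinary proteins, had 0.0548 to 0.179 CPM in the control libraries and 1.34 to 2.17 CPM in the endostatin libraries (DESeq2 adjusted p = 0.000192, log2 fold change 4.28 ± 0.77, higher in 4 of 4). Major urinary proteins are made mainly in liver; the sum of hepatocyte transcripts was 193.1 TPM in control 1, where Mup17 stood at 0.179 CPM, and 25 TPM in endostatin 3, where it stood at 1.34 CPM. Trpc2 (ENSMUSG00000100254; DESeq2 adjusted p = 0.000192) had 0 counts in 4 of 4 control libraries and 0.855 to 1.9 CPM after endostatin, and it was the gene called by limma-voom with sample quality weights (adjusted p = 0.0315). Both values are uncertain, because Mup17 belongs to a family of near-identical genes and Trpc2 overlaps other transcripts, and both levels are near 1 CPM. The predicted gene Gm7694 had a log2 fold change of 0.76 ± 0.15 (DESeq2 adjusted p = 0.00215), and the pseudogene Gm28438 one of -0.82 ± 0.18 (DESeq2 adjusted p = 0.0137). Gm28438 stood at 132 to 264 CPM in batch 1 and 36.2 to 82.5 CPM in batch 2, where the mitochondrial percentage was also lower. Whether it repeats the mitochondrial signal was not tested. In edgeR's test the adjusted p of Mup17 was 0.409, and it was 1.00 for the other 3.

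The genes with the smallest p in each direction are given as values that did not pass the threshold. St6galnac5 (ENSMUSG00000039037), a sialyltransferase, had 8.01 ± 1.37 CPM in the control group and 16.0 ± 4.0 CPM after endostatin, a log2 fold change of 1.01 ± 0.21 (unadjusted p = 0.00130). Ackr3, a scavenging receptor for the chemokine CXCL12, had 37.1 ± 2.7 and 52.7 ± 8.1 CPM, a log2 fold change of 0.50 ± 0.11. Vgll3, a cofactor of TEAD transcription factors, had a log2 fold change of 0.63 ± 0.15, and Nos1ap, an adaptor of neuronal nitric oxide synthase, one of 0.69 ± 0.15. Ugt1a1, the enzyme that conjugates bilirubin and that shares exons with its neighbours, had 1.85 ± 0.44 and 5.92 ± 2.65 CPM. F10, coagulation factor X, had 0.763 ± 0.285 and 2.07 ± 0.48 CPM. Both genes are expressed in liver; the sum of hepatocyte transcripts was 25 TPM in endostatin 3, where Ugt1a1 stood at 4.43 CPM and F10 at 1.55 CPM, and 1339 TPM in endostatin 4, where they stood at 9.64 and 2.71 CPM.

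Among genes with lower levels, Ankrd9 (ENSMUSG00000037904) had 8.12 ± 1.72 CPM in the control group and 3.81 ± 0.90 CPM after endostatin, a log2 fold change of -1.10 ± 0.22 (unadjusted p = 0.00122). Ide (ENSMUSG00000056999), which encodes the insulin-degrading enzyme, had 124.5 ± 21.1 and 80.5 ± 10.2 CPM, a log2 fold change of -0.62 ± 0.14 with a 95% interval from -0.93 to -0.31. Usp2, a deubiquitinating enzyme with a daily rhythm, had a log2 fold change of -0.87 ± 0.20, Cdk6, a cell cycle kinase, one of -0.37 ± 0.08, and Tle1, a transcriptional corepressor, one of -0.35 ± 0.08. The mitochondrially encoded mt-Nd3, a subunit of respiratory complex I, had -0.61 ± 0.14. All 12 genes had the same sign in both batches, with log2 fold changes in batch 1 and batch 2 of 0.81 and 1.22 for St6galnac5, 0.40 and 0.60 for Ackr3, -0.98 and -1.22 for Ankrd9 and -0.48 and -0.76 for Ide. These genes were ranked on the same libraries, which favours such a match.

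Genes fixed for their bearing on endostatin and adipose tissue showed intervals that include 0, with the exception of Irs2 and Ccl2. Col18a1 itself had a log2 fold change of 0.13 ± 0.15. Kdr, the main receptor of vascular endothelial growth factor, had -0.11 ± 0.11, with an interval from -0.37 to 0.15, and Pecam1, an endothelial adhesion molecule, had 0.06 ± 0.10, from -0.18 to 0.29. Vegfa had 198.8 ± 32.5 and 243.6 ± 38.5 CPM, a log2 fold change of 0.30 ± 0.16. Adipoq had 0.03 ± 0.28, Lep (leptin) 0.06 ± 0.48, and the lipases Pnpla2 and Lipe -0.09 ± 0.36 and 0.03 ± 0.24. Ucp1, the uncoupling protein of brown and beige fat, had -2.02 ± 1.64, with 67.6 CPM in control 3 and 16.7 CPM in endostatin 4 against 0 to 6.53 CPM elsewhere. The insulin receptor substrate Irs2 had 145.0 ± 36.2 and 208.6 ± 25.2 CPM, a log2 fold change of 0.53 ± 0.19 (unadjusted p = 0.0239). The chemokine Ccl2 had 0.881 ± 0.158 and 2.14 ± 0.95 CPM, a log2 fold change of 1.23 ± 0.41 (unadjusted p = 0.0174). The early response genes Fos and Egr1 had 0.40 ± 0.29 and 0.33 ± 0.24, the clock-controlled Per1 and Dbp -0.15 ± 0.16 and -0.37 ± 0.26, and Fkbp5, induced by glucocorticoids, -0.23 ± 0.33. Pdk4, which restrains pyruvate oxidation in fasting, had 0.22 ± 0.37, with -0.70 in batch 1 and 1.12 in batch 2.

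**Figure D2:**
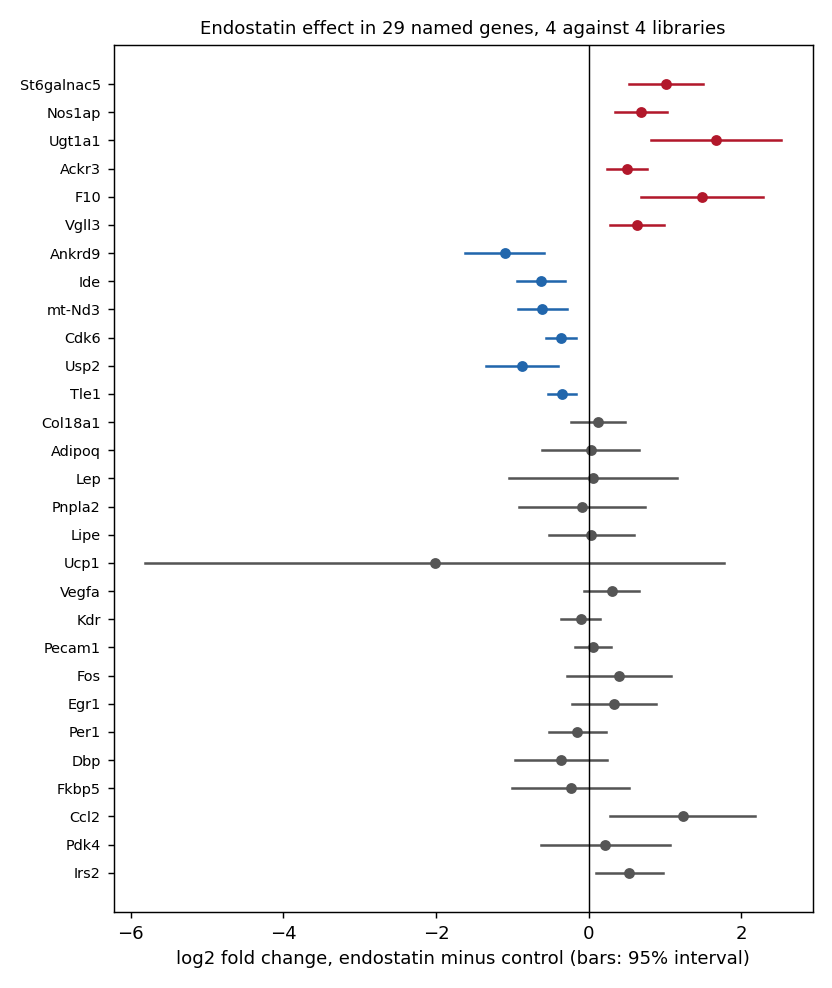
Log2 fold change, endostatin minus control, with its 95% interval (bars) for the 6 genes of each direction with the smallest p (red, higher; blue, lower) and the genes reported whatever their values (grey), 4 against 4 libraries. Ide lies at -0.62 and St6galnac5 at 1.01, and the interval of Ucp1 runs from -5.81 to 1.77.

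Of the 36 gene lists tested with a preset correlation, 14 passed camera's threshold, 8 with higher and 6 with lower levels after endostatin; with an estimated correlation 0 passed, and fry called 0. No member of any list passed edgeR's test over all genes tested. Adjusted over the list alone, 1 member passed, mt-Nd3 (edgeR adjusted p = 0.0304).

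Genes of collagens and matrix remodelling, of fibroblasts and of mesothelium passed with higher levels, with the preset correlation only. Endothelial, lymphatic and pericyte markers did not pass. All 30 tested genes of collagens and matrix remodelling had positive log2 fold changes, with a median of 0.26 (camera adjusted p = 4.88e-08; adjusted p = 0.338 with an estimated correlation). Loxl1, which crosslinks elastin, had 104.6 ± 11.2 and 148.5 ± 27.4 CPM, and Ctss, a lysosomal protease, 29.9 ± 6.5 and 47.0 ± 12.4 CPM. Among fibroblast and progenitor markers, 14 of 15 were positive, with a median of 0.28 (camera adjusted p = 2.04e-05; adjusted p = 0.470 with an estimated correlation). Fbn1, which encodes fibrillin, had 428.4 ± 53.5 and 677.5 ± 221.5 CPM. Of 12 mesothelial genes 9 were positive, with a median of 0.22 (camera adjusted p = 0.0366; adjusted p = 0.704 with an estimated correlation). In batch 1 the medians of these lists were 0.02, 0.03 and -0.05, and in batch 2, which holds both libraries with raised oviduct and uterus markers, they were 0.47, 0.64 and 0.42. Without both of those libraries the collagen median was 0.24, with 28 of 30 genes positive (camera adjusted p = 1.22e-05, and 0.704 with an estimated correlation). The collagen list passed camera in 23 of 23 alternatives with the preset correlation. The mesothelial call ended without any of control 2, control 4, endostatin 1, endostatin 3 and endostatin 4 (medians 0.19, 0.02, 0.14, 0.19 and 0.21, adjusted p = 0.0921, 0.86, 0.179, 0.0584 and 0.421), without both of control 3 and endostatin 4, where the median stayed at 0.22 (adjusted p = 0.0651), and with sample quality weights, library size only or no low-count filter (0.16, 0.23 and 0.24, adjusted p = 0.197, 0.0529 and 0.0586). Without control 1 and control 4, both with raised muscle markers, the mesothelial and fibroblast calls ended (medians 0.06 and 0.11, adjusted p = 0.693 and 0.178), and the collagen median was 0.17 (adjusted p = 0.00301). The fibroblast median was 0.10 without endostatin 4 (adjusted p = 0.0176), 0.12 without both of control 3 and endostatin 4 (adjusted p = 0.0446) and 0.42 without control 2 (adjusted p = 7.04e-08). The mesothelial median was 0.41 without control 3 (adjusted p = 0.00435) and 0.43 without endostatin 2 (adjusted p = 2.49e-05).

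Macrophage, mast cell and eosinophil, NF-kB and interferon genes also passed with higher levels, with the preset correlation only. Neutrophil, T and NK cell, and B and plasma cell markers did not pass. Of 16 macrophage markers, 13 were positive, with a median log2 fold change of 0.34 (camera adjusted p = 5.69e-05; adjusted p = 0.470 with an estimated correlation), and Cd68 had 21.4 ± 4.4 and 35.7 ± 11.4 CPM. All 7 markers of mast cells and eosinophils were positive, with a median of 0.43 (camera adjusted p = 0.00462; adjusted p = 0.470 with an estimated correlation), among them Cma1, a mast cell protease, with 4.98 ± 1.89 and 7.57 ± 2.34 CPM. Of 17 genes of NF-kB signalling and inflammatory mediators, 16 were positive, with a median of 0.27 (camera adjusted p = 3.08e-06; adjusted p = 0.194 with an estimated correlation), and Nfkb2 had 30.3 ± 2.2 and 35.7 ± 2.7 CPM. Of 25 interferon response genes 20 were positive, with a median of 0.13 (camera adjusted p = 0.0181; adjusted p = 0.576 with an estimated correlation), and Ifit3 had 21.2 ± 7.3 and 28.5 ± 3.1 CPM. The medians in batch 1 were -0.02, 0.04, 0.06 and -0.06, and in batch 2 they were 0.70, 0.86, 0.40 and 0.30. Without control 3 and endostatin 4, the libraries with raised oviduct and uterus markers, the macrophage and interferon calls ended (medians 0.13 and 0.08, adjusted p = 0.134 and 0.589), and the mast cell call ended without control 4 (0.23, adjusted p = 0.114). Without control 1 and control 4 the 4 calls ended (adjusted p = 0.0885, 0.693, 0.0546 and 0.433); the macrophage median stayed at 0.34, and those of the mast cell, NF-kB and interferon lists were 0.13, 0.17 and 0.04. The interferon call ended also without any of control 3, control 4, endostatin 3 and endostatin 4 (medians 0.12, 0.11, 0.11 and 0.07, adjusted p = 0.346, 0.171, 0.195 and 0.226) and with sample quality weights (0.08, adjusted p = 0.264). Without control 2 the macrophage, mast cell and interferon medians were 0.52, 0.72 and 0.21 (adjusted p = 1.21e-07, 9.87e-05 and 0.000479), and without both of control 3 and endostatin 4 the NF-kB median was 0.17 (adjusted p = 0.000186).

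Immediate early genes, which respond to stimuli within minutes to hours, passed with higher levels, with the preset correlation only. Of 27 genes, 22 were positive, with a median log2 fold change of 0.30 (camera adjusted p = 3.05e-07, and 0.194 with an estimated correlation). Egr2 had 1.38 ± 0.54 and 3.36 ± 1.10 CPM, a log2 fold change of 1.27 ± 0.37, and the transcription factor Klf4 had 61.2 ± 7.5 and 83.3 ± 9.8 CPM, a log2 fold change of 0.44 ± 0.12. Among members with negative values, Srf had -0.16 ± 0.14 and Myc -0.08 ± 0.18. The median was 0.15 in batch 1 and 0.28 in batch 2, and 18 of 27 genes had the same sign in both. It was 0.18 both without control 4 (adjusted p = 0.000187) and without control 1 and control 4 (adjusted p = 0.024).

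Mitochondrial transcripts passed with lower levels, with the preset correlation only. All 13 mitochondrially encoded genes were negative, with a median log2 fold change of -0.43 (camera adjusted p = 1.41e-13; adjusted p = 0.338 with an estimated correlation). mt-Atp8, a subunit of ATP synthase, had 361.4 ± 175.7 and 272.9 ± 210.4 CPM. The nuclear-encoded list of oxidative phosphorylation had 26 tested entries for 25 gene symbols, because Atp5o has duplicate entries. Of the 26, 25 were negative, with a median of -0.20 (camera adjusted p = 2.74e-06, and 0.573 with an estimated correlation). Cox6c, a subunit of cytochrome c oxidase, had 71.5 ± 14.6 and 54.1 ± 15.7 CPM. The medians were -0.20 and -0.18 in batch 1 and -0.66 and -0.20 in batch 2, and every gene of both lists had the same sign in both batches. The nuclear-encoded median was -0.12 without control 1 (adjusted p = 0.0112) and -0.30 without control 3 (adjusted p = 3.41e-10). The nuclear-encoded call ended without control 4 (median -0.06, adjusted p = 0.0992), and the median turned to 0.07 without control 1 and control 4 (adjusted p = 0.316), the libraries whose skeletal muscle markers summed to 238.1 and 464.6 TPM against 35.2 to 108.3 TPM in the other 6.

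Lipogenic, thermogenic, clock and muscle genes passed with lower levels, with the preset correlation only. Of 22 genes of fatty acid and triglyceride synthesis, 20 were negative, with a median log2 fold change of -0.42 (camera adjusted p = 0.000262; adjusted p = 0.573 with an estimated correlation). Aacs, which makes acetoacetyl-CoA in the cytosol, had 372.9 ± 114.7 and 247.8 ± 57.8 CPM, and Agpat2, an acyltransferase of glycerolipid synthesis, 521.3 ± 158.0 and 384.0 ± 121.0 CPM. Of 17 thermogenic genes 14 were negative, with a median of -0.26 (camera adjusted p = 0.0112; adjusted p = 0.573 with an estimated correlation); Cox7a1 had 4.17 ± 1.69 and 2.51 ± 0.44 CPM. Slc27a2, a fatty acid transporter of liver and kidney and the list's highest member, had a log2 fold change of 2.33 ± 1.38. Of 21 clock genes 16 were negative, with a median of -0.26 (camera adjusted p = 0.00682; adjusted p = 0.470 with an estimated correlation), among them the repressor Cry1 with -0.46 ± 0.18, while Clock had 0.22 ± 0.08. All 8 skeletal muscle markers were negative, with a median of -2.78 (camera adjusted p = 0.0115; adjusted p = 0.576 with an estimated correlation), and Tnnt3, a fast muscle troponin, had 7.66 ± 8.32 and 1.08 ± 0.82 CPM. The medians of these lists were -0.11, -0.10, -0.04 and -1.34 in batch 1 and -0.65, -0.51, -0.42 and -4.31 in batch 2. The lipogenic call ended without control 4 (median -0.25, adjusted p = 0.156) or endostatin 4 (-0.13, adjusted p = 0.263), with medians of -0.26 without control 1 (adjusted p = 0.0127), -0.24 without both of control 3 and endostatin 4 (adjusted p = 0.0345) and -0.28 with no batch term (adjusted p = 0.000584). The clock call ended without control 4 (-0.09, adjusted p = 0.15), endostatin 4 (-0.15, adjusted p = 0.0512) or both of control 3 and endostatin 4 (-0.19, adjusted p = 0.0774). The thermogenic call ended without control 3 (-0.17, adjusted p = 0.358) or endostatin 3 (-0.11, adjusted p = 0.362) and with sample quality weights (-0.12, adjusted p = 0.164). The thermogenic median was -0.44 without control 4 (adjusted p = 0.0277), -0.55 without endostatin 4 (adjusted p = 0.000774), -0.51 without control 1 and control 4 (adjusted p = 0.00272) and -0.55 with length offsets (adjusted p = 0.0132). The muscle call ended without control 1 (-2.51, adjusted p = 0.221) or control 4 (-1.02, adjusted p = 0.699) and with limma-voom (-1.23, adjusted p = 0.0557). The muscle median was -1.79 with sample quality weights, -1.59 with a block on the replicate number and -1.80 with 1 surrogate variable (adjusted p = 0.00254, 0.000903 and 0.0122). Without both of control 1 and control 4 the lipogenic and clock calls ended (medians 0.005 and -0.09, adjusted p = 0.935 and 0.375), and the muscle median turned to 0.73 (camera adjusted p = 0.024; adjusted p = 0.744 with an estimated correlation).

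The other lists did not pass. Medians of metabolic lists were -0.12 for fatty acid oxidation (camera adjusted p = 0.0545), -0.15 for cholesterol synthesis (0.0653), -0.04 for lipolysis (0.821), -0.03 for adipocyte identity (0.915) and 0.10 for insulin and FoxO responsive genes (0.354). Cpt1a, which admits fatty acids to mitochondria, had 82.6 ± 6.0 and 105.3 ± 15.4 CPM against a negative median of its list. The angiogenic ligands and receptors had a median of 0.09 over 37 genes, 24 of them positive (camera adjusted p = 0.0545); Thbs2, an anti-angiogenic thrombospondin, had 114.5 ± 11 and 348.9 ± 299.6 CPM, with log2 fold changes of 0.49 in batch 1 and 2.16 in batch 2. The 18 endothelial markers had a median of 0.04 (0.477), lymphatic endothelial markers 0.12 (0.988), and pericytes and smooth muscle 0.06 (0.915). Among signalling lists the medians were 0.11 for glucocorticoid responsive genes (0.413), 0.06 for MAPK feedback regulators (0.117), -0.03 for hypoxia targets (0.69), 0.06 for TGF-beta responsive genes (0.137), 0.01 for the integrated stress response (0.915) and -0.03 for the unfolded protein and heat shock response (0.756). Among markers of other cells they were 0.06 for neutrophils (0.752), 0.02 for T and NK cells (0.546), 0.14 for B and plasma cells (0.106), 0.02 for erythroid cells (0.827), 0.24 for nerve and Schwann cells (0.355), 0.16 for ovary (0.0545) and -0.67 for oviduct and uterus (0.0857). Median and test differed in sign for lipolysis, adipocyte identity, hypoxia targets and pericytes, and median and mean for the integrated stress response, the unfolded protein response, erythroid and nerve lists and hypoxia targets. The epididymis and testis, pancreas and sex-linked lists had 2, 1 and 2 tested members and were not tested as sets; their medians were -0.12, -0.19 and 0.33.

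Among the lists that did not pass, some passed camera with a preset correlation under other settings. With an estimated correlation 0 lists passed when any 1 library or either of the 2 pairs was left out (lowest adjusted p = 0.106). Fatty acid oxidation genes passed in 13 of 23 alternatives, with lower levels. The median was -0.27 without control 3 (adjusted p = 3.9e-11) and -0.17 without endostatin 4 (adjusted p = 0.0176). It was -0.15 without endostatin 3 (adjusted p = 0.0407) and -0.29 without both of control 3 and endostatin 4 (21 of 22 negative, adjusted p = 9.33e-11). For these, adjusted p = 0.341, 0.799, 0.799 and 0.704 with an estimated correlation. The median was -0.01 without control 4 (adjusted p = 0.87). Angiogenic ligands and receptors passed in 10 of 23 alternatives, with higher levels and medians from 0.06 to 0.12 over all 23. The adjusted p was 0.00829 without endostatin 4, 0.028 without control 1, 0.0319 with a block on the replicate number and 0.35 without endostatin 3. Without endostatin 4, without control 1 and with the block, adjusted p = 0.255, 0.405 and 0.543 with an estimated correlation. Ovary markers passed in 11 of 23, with medians of 0.38, 0.32, 0.05 and 0.26 without control 2, control 3, endostatin 3 and endostatin 4 (adjusted p = 0.0289, 0.00338, 0.0116 and 0.0176; adjusted p = 0.454, 0.341, 0.609 and 0.529 with an estimated correlation). Cholesterol synthesis genes passed in 8 of 23, with medians of -0.38, -0.28 and -0.48 without control 2, endostatin 2 and endostatin 3 (adjusted p = 9.87e-05, 0.0252 and 0.000855; adjusted p = 0.455, 0.75 and 0.676 with an estimated correlation). Adipocyte identity genes passed with lower levels without control 3 (-0.24, adjusted p = 5.71e-06) or both of control 3 and endostatin 4 (-0.21, adjusted p = 0.000221), and with higher levels without control 4 (0.19, adjusted p = 0.00522) or both of control 1 and control 4 (0.34, 20 of 20 positive, adjusted p = 0.000124). For these 4 calls, adjusted p = 0.473, 0.704, 0.741 and 0.744 with an estimated correlation. Lipolysis genes likewise had -0.16 without control 3 (adjusted p = 0.00108) and 0.20 without control 1 and control 4 (adjusted p = 0.0252; adjusted p = 0.473 and 0.744 with an estimated correlation). Glucocorticoid responsive genes passed without control 1 (0.19, adjusted p = 0.0221) or endostatin 1 (0.20, adjusted p = 0.00421), and oviduct and uterus markers without control 4 (-0.69, adjusted p = 0.013) or endostatin 1 (-0.99, adjusted p = 0.0184); adjusted p = 0.663, 0.562, 0.741 and 0.571 with an estimated correlation. B and plasma cell markers passed without endostatin 2 (0.34, adjusted p = 0.0242) or endostatin 3 (0.14, adjusted p = 0.0266); adjusted p = 0.412 and 0.627 with an estimated correlation. TGF-beta responsive genes passed without control 3 (0.13, adjusted p = 0.0484) and neutrophil markers, with lower levels, without endostatin 4 (-0.77, adjusted p = 0.0434); adjusted p = 0.502 and 0.797 with an estimated correlation. Medians of lists that did not pass also changed sign when libraries were left out. Without endostatin 4 the lymphatic median was -0.94 (adjusted p = 0.226) and the pericyte median -0.24 (adjusted p = 0.201). Without both of control 3 and endostatin 4 the oviduct and uterus median was 0.35 (adjusted p = 0.475) and the glucocorticoid median -0.16 (adjusted p = 0.21).

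**Figure D3:**
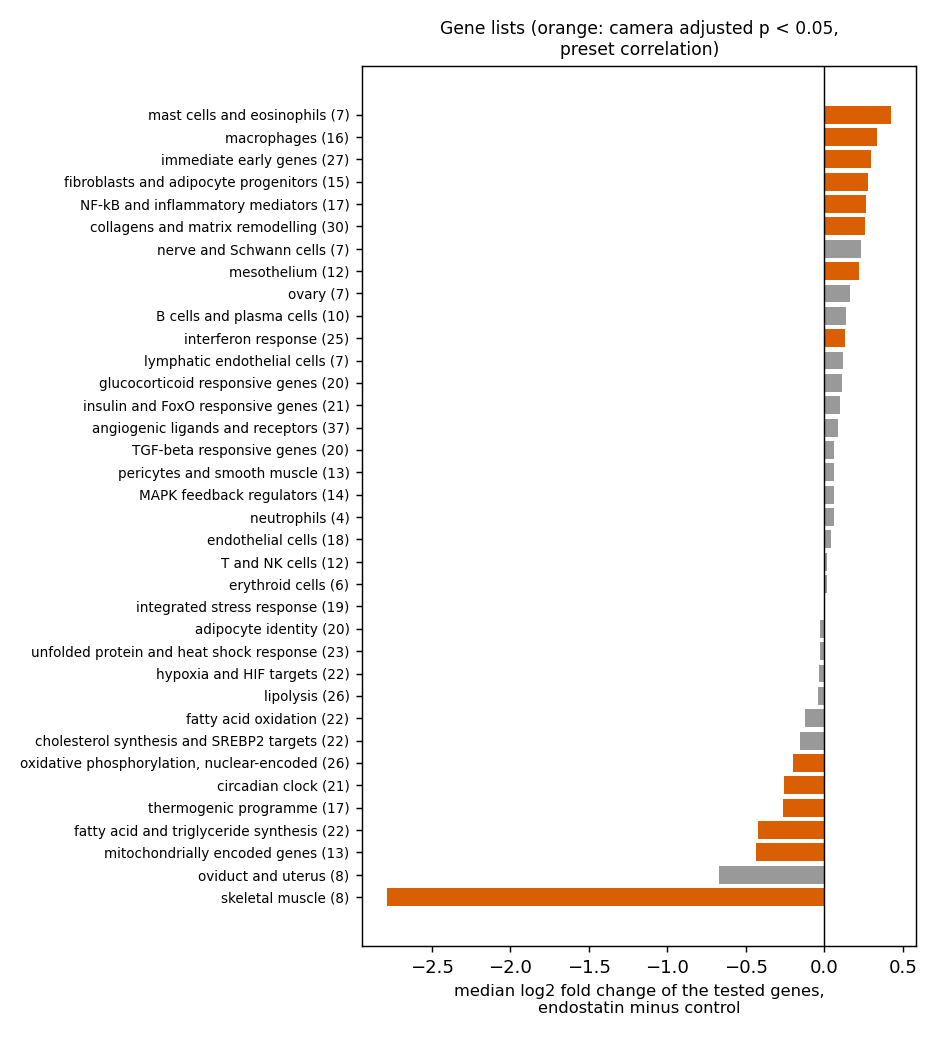
Median log2 fold change, endostatin minus control, of the tested genes of each list (number of genes in parentheses; orange, camera adjusted p under 0.05 with a preset correlation; grey, not past it). Skeletal muscle lies at -2.78 and mast cells and eosinophils at 0.43, and with an estimated correlation 0 lists pass.

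The balanced batches allow the endostatin effect to be compared between them. Across genes, which are not independent replicates, the log2 fold changes of batch 1 and batch 2 had a Pearson correlation of 0.169 and a Spearman correlation of -0.054, and 47.7% of genes had the same sign. Over the 9996 genes with at least 10 CPM the Pearson correlation was -0.057. In edgeR's interaction test 0 genes passed, with a lowest adjusted p of 0.471 and 527 genes at an unadjusted p under 0.05; DESeq2 called 26. The named genes with the smallest interaction p were the olfactory receptor Olfr1033, with -0.46 in batch 1 and 0.87 in batch 2, Pdk4, Smpd3 (-0.46 and 1.17) and the zinc transporter Slc39a8 (-0.35 and 1.27), and in the other direction Lars2 (0.87 and -0.38), Olfr1385 (0.33 and -0.35), Akap5 (0.56 and -2.13) and Zfp846 (0.44 and -0.63). Over all genes, the Pearson correlation between batches was -0.053 without endostatin 4, 0.010 without endostatin 2, 0.088 without control 4 and 0.312 without control 3.

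Between batches, 1 gene rose and 5 fell in batch 2 past edgeR's threshold, with 1513 genes at an unadjusted p under 0.05. Rasd1 (ENSMUSG00000049892), a Ras-related protein induced by glucocorticoids, fell from 100.8 to 127.8 CPM in the libraries of batch 1 to 28.3 to 41.4 CPM in batch 2, a log2 fold change of -1.68 ± 0.12 (edgeR adjusted p = 0.00902). mt-Nd3 fell by 1.58 on the log2 scale (edgeR adjusted p = 0.0178), in 4 of 4 libraries against all 4 of batch 1. Further features past the threshold, chosen after their values were seen, included the pseudogenes Gm28438 (-1.85 ± 0.17) and Rpl15-ps3 (1.65 ± 0.16) and 1 transcript without an annotation match. Among named genes that did not pass, mt-Atp8 had -1.75 ± 0.22, Myh14 0.69 ± 0.09, Errfi1 1.03 ± 0.17, Tent5b 1.25 ± 0.21 and Cnn2 0.45 ± 0.07. The count was 171 with DESeq2 and 10 with limma-voom, and it was 0 without control 1, control 2, endostatin 2 or endostatin 3, 3 without endostatin 1 and 18 without endostatin 4.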

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

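The split tests were written before any split was run, when the counts of the real grouping were known; the tests of liver, epithelial and mitochondrial transcripts, and the marker lists they use, were chosen after the results were seen.

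Transcripts typical of liver varied between libraries, with Alb at 88.6, 51.1, 10 and 18.3 TPM in control 1 to 4 and 194.2, 257, 17.2 and 487.4 TPM in endostatin 1 to 4. In the 5 libraries with the highest sums the 26 genes kept nearly 1 ratio. The SD of the log2 ratio to endostatin 4 was 0.3 in endostatin 2, 0.36 in endostatin 1, 0.44 in control 1 and 0.59 in control 2. A candidate explanation for those libraries is RNA from hepatocytes in the samples. In control 3, control 4 and endostatin 3 the SD was 1.66, 2.08 and 1.86 over the 15, 14 and 15 genes above 0. Their sums were only 20.4, 31.9 and 25 TPM, with low counts per gene, so the SD cannot decide there. A response of the adipose tissue to endostatin stays open as well: the mean log2 difference of the sums was 2.32, the exact two-sided permutation p over 70 arrangements was 0.171, and endostatin 3, at 25 TPM, lay within the control range. In the library with the lowest sum, control 3, 3 of the 26 genes, Alb, Apoa2 and Apoc3, were still over 1 TPM. Ugt1a1 and F10 may carry part of this signal, which was not tested gene by gene.

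Transcripts of oviduct and uterus stood apart in control 3 (Msx1 162.4, Pgr 97.2, Ltf 87.9 and Pax8 40.3 TPM) and in endostatin 4 (Ltf 298.3 and Pax8 12.8 TPM). In control 3, 12 of 13 genes of the list were at over 2 times their median in the 6 other libraries, which is consistent with tissue of the oviduct or uterus in that sample. In endostatin 4 the number was 8 of 13, among them Wnt7a at only 0.29 TPM, which leaves this open. Endostatin 1, one of the 6 other libraries, held some of these transcripts at a low level (Pgr 11.7 and Msx1 8.72 TPM). More mesothelium as the whole cause is argued against by the 7 mesothelial markers outside the keratins, at 1.12 times the median of the others in control 3 and 1.49 times in endostatin 4 (range 0.75 to 1.58), while 5 keratins and junction genes were at 14.9 and 7.2 times. The reading of endostatin 4 depended on the criterion: under a later draft of it the mesothelial test was undecided.

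Mitochondrially encoded transcripts were lower in batch 2, with a median log2 difference of -1.09 over the 13 genes. Loss of transcripts under 1000 bases as a whole in that batch is argued against by 1859 nuclear protein-coding genes of that length. Their median was 0.01 with quartiles of -0.14 and 0.19. Loss limited to far shorter transcripts was not tested and stays open for part of the fall, which ranged from -1.75 to -0.7 over the 13 genes. Fewer mitochondria, with nuclear-encoded respiratory genes falling by as much, are argued against by the 26 tested entries of such genes, whose median was -0.17. They ranged from -0.68 to -0.02, all above the mitochondrially encoded median. Each was nevertheless lower in batch 2, so a smaller loss of mitochondria stays open. The bootstrap 95% interval of -0.22 to -0.11 resamples genes with an estimated inter-gene correlation of 0.73, so it does not measure the spread between samples. In all 4 libraries of batch 2 the mitochondrial percentage was below every library of batch 1, so handling or sequencing that differed between the batches cannot be told apart from other differences between the batches, because nothing else distinguishes them in the labels. Other biological differences between the batches were not tested.

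Within a group of 4 libraries, 19 of 428 groups of values had a library far from the other 3, by the gap to the nearest library as a share of the range; chance gives about 1 in 20. Control 3 was lowest in Adipoq (0.903), Pnpla2 (0.851), Lipe (0.864), Plin4 (0.841) and the lipolysis list (0.95), and highest in Slc7a11 (0.874), Sox17 (0.917), Flt4 (0.912) and the oviduct and uterus list (0.904). Endostatin 4 was highest in Lcn2 (0.973) and the neutrophil list (0.842), to which Lcn2 belongs. Endostatin 3 was highest in Col18a1 (0.833) and Cd3e (0.972), endostatin 2 highest in Trac (0.919) and endostatin 1 lowest in Mustn1 (0.908). Control 1 was highest in Cry1 (0.864), control 2 highest in Cpa3 (0.973), and control 4 lowest in Mpeg1 (0.894) and Jchain (0.912).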

How the results depend on the processing

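Leaving out control 3 with endostatin 4, and control 1 with control 4, was chosen after the data were seen; the other alternatives were planned. In edgeR 0 genes were higher and 0 lower after endostatin (485 at an unadjusted p under 0.05); the counts were also 0 under the alternatives run, except DESeq2 (3 higher, 1 lower) and limma-voom with sample quality weights (1 higher). The count of genes whose endostatin effect differed between batches was 26 with DESeq2 and 0 in edgeR. The count of genes differing between batches, 6 in edgeR, was 2 with library size only, 171 with DESeq2, 10 with limma-voom, 20 with sample quality weights, 11 with no low-count filter, 3 with protein-coding genes only, 2 with 1 surrogate variable, 27 without control 3 and endostatin 4, 0 without control 1 and control 4, and 0 to 18 when 1 library was left out. The correlation of endostatin log2 fold changes between batches ranged from -0.053 to 0.312 when 1 library was left out. Lists that turned and were called in at least 1 of the fits compared were adipocyte identity with sample quality weights (-0.16, adjusted p = 0.0147), adipocyte identity and lipolysis without control 3 and endostatin 4 (-0.206, adjusted p = 0.000221, and -0.107, adjusted p = 0.00197; without control 1 and control 4 they were called the other way, at 0.343, adjusted p = 0.000124, and 0.204, adjusted p = 0.0252; adjusted p = 0.704 for both without the former pair and 0.744 for both without the latter with an estimated correlation), and nuclear-encoded oxidative phosphorylation and skeletal muscle without control 1 and control 4 (0.074, adjusted p = 0.316, and 0.733, adjusted p = 0.024). When 1 library was left out, the median of lipolysis ranged from -0.156 (without control 3, adjusted p = 0.00108) to 0.124, of adipocyte identity from -0.243 (without control 3, adjusted p = 5.71e-06) to 0.193, of mesothelium from 0.021 (without control 4, where the test turned) to 0.432, and of neutrophils from -0.772 (without endostatin 4, adjusted p = 0.0434) to 0.414. Of the 22 lists not called with all libraries, 19 had a median of the other sign under at least 1 alternative. The cause of these changes was not tested, apart from the smaller number of libraries or genes that some settings bring. The number of lists called by camera ranged from 9 to 17 over the alternatives with a preset correlation; of the 14 calls, 11 held with sample quality weights, 7 without control 4, 10 without endostatin 4, 10 without control 3 and endostatin 4, 4 without control 1 and control 4, and 0 with an estimated correlation. Replicate numbers gave no sign of pairing the libraries. After the group mean of each gene was subtracted, treated and control libraries of the same number had correlations of 0.211, 0.144, -0.073 and -0.295. With the mean of each group within its batch subtracted instead, these were 0.012, 0.012, -0.352 and -0.352. The depth gave a floor of 0.126 to 0.19 CPM in a library, which limits values such as those of Mup17 and Trpc2.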

Other observations

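The split tests were written before any split was run, when the counts of the real grouping were known; the gene groups compared between batches were fixed before the data were examined, and the erythroid comparison was singled out after its values were seen.

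Between batches 14 of 36 lists passed camera with a preset correlation, 7 with higher and 7 with lower levels in batch 2; with an estimated correlation 0 passed (lowest adjusted p = 0.282). Clock genes had a median log2 difference of -0.54 in batch 2 against batch 1 (camera adjusted p = 1.18e-07; adjusted p = 0.282 with an estimated correlation), among them Per3 at -0.96 ± 0.21 and Dbp at -0.97 ± 0.26, while Arntl, which drives the opposite phase, had 1.25 ± 0.39. Glucocorticoid responsive genes had a median of 0.80 (camera adjusted p = 1.18e-07; adjusted p = 0.659 with an estimated correlation), and Pdk4 had 1.47 ± 0.37. Rasd1, itself induced by glucocorticoids, differed the other way, at -1.68 ± 0.12. Besides these and the mitochondrially encoded list, 11 lists passed, among them immediate early genes (median 0.30, camera adjusted p = 0.000186; adjusted p = 0.352 with an estimated correlation), and, each with adjusted p = 0.681 with an estimated correlation, collagens (0.23, camera adjusted p = 0.000638), fatty acid and triglyceride synthesis (-0.47, camera adjusted p = 0.000321), nuclear-encoded oxidative phosphorylation (-0.17, camera adjusted p = 0.000321) and the unfolded protein response (0.14, camera adjusted p = 0.00245). The hour of collection is not given per batch in the labels.

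All 6 erythroid genes had opposite signs of the endostatin log2 fold change in the batches, with medians of -0.44 in batch 1 and 0.52 in batch 2. Hbb-bs, a beta globin, had -0.44 and 0.65 in the 2 batches (edgeR interaction adjusted p = 0.997), and Hba-a2, an alpha globin, -0.45 and 0.60. These genes had an estimated inter-gene correlation of 0.936 and do not make 6 separate observations.

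For the count of genes past the threshold between endostatin and control, splits of the libraries decide nothing, since 35 of 35 must give at least the real 0 of edgeR (485 genes at an unadjusted p under 0.05; 4 called by DESeq2 and 0 by limma-voom); the highest other count was 5, for the split that follows the batches. Chance could not be excluded for the genes at an unadjusted p under 0.05 or for the lists. For the 485 genes at an unadjusted p under 0.05, 19 of 35 splits gave as many. The highest other count was 2433, for the split of control 1, control 4, endostatin 2 and endostatin 3 from the rest. Those 4 libraries had the lowest scores on the first principal component, -34.0 to -16.7, against -14.1 to 71.5 in the rest. The count of 2433 may point to a structure of the samples other than treatment, whose source was not tested. For the 14 called lists, 10 of 35 splits gave as many, with a highest other count of 18, and the split that follows the batches gave 14 as well. For the 6 genes past the threshold between batches, 1 of 35 splits, the real one, gave as many, and the highest other count was 1. No smaller share can occur with 35 splits, so chance was made less likely for this count but not excluded. Nor was chance excluded for the 1513 genes at an unadjusted p under 0.05 between batches. There, 6 of 35 splits gave as many, with a highest other count of 2401. The 6 calls fell to 0 without control 1, control 2, endostatin 2 or endostatin 3.

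Markers of kidney and of mammary gland, 7 genes each, had 0 genes over 1 TPM in any library. Of 12 pancreatic acinar markers, 8 had less than 1 count over all libraries.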
